A study of Mus musculus with 9 samples.

How the data were processed

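The study deposited 1 table of gene expression for CD8+ T cells isolated from B16F10 melanomas of C57BL/6 mice, 5 WT and 4 IL27ra KO libraries, grouped by the genotype in the labels. Per the labels' protocols, bulk T cells were lysed, RNA was cleaned on SPRI beads and libraries were made with an adaptation of SMART-Seq 2, a method that copies full-length polyadenylated RNA and amplifies it by PCR. How the cells were isolated, the strand setting and the sequencing layout are not given in the sources used here. SMART-Seq 2 has no molecular identifiers, so PCR copies count as separate fragments and add to the spread between libraries.

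Per the labels, the deposited values are gene-level FPKM from RSEM with TMM normalization, which scales libraries to a trimmed mean of gene ratios. The submitters' processing notes name TopHat, RSEM and DESeq and the mouse build mm9, without versions, roles or order. RSEM divides reads that match several genes among them, so values of near-identical genes can trade with each other. TMM assumes that most genes keep their level, and a change in the makeup of the cells in a library moves the values of all of its genes. The table holds 23366 gene symbols without duplicates, of which 21732 matched a table of current mouse gene names, and it has 0 columns of other samples. The reference genome at hand is of another build than mm9, so no coordinates are printed.

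The FPKM values are not whole counts, so no count test was used. In single-transcript genes, low FPKM values sat near whole multiples of what 1 fragment is worth. Transcript lengths for 3810 genes, from GENCODE release M21, gave 0.244 to 0.572 FPKM for 1 fragment in 1 kb, which implies 1750000 to 4100000 fragments per library. Between 65.1% and 72.2% of the low values lay within 0.1 of a whole multiple, against 20% for evenly spread values. Because lengths come from another build and RSEM splits fragments, these depths are estimates. Rn45s, the precursor of ribosomal RNA, took 23.9% to 53.8% of a library's summed FPKM, most in WT replicates 3 and 4 (53.8% and 50.8%). The sums ran from 263888 to 431078, so totals are a poor scale for these libraries.

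From the deposited FPKM, log2(FPKM + 1) was computed and genes with a mean of at least 1 FPKM over the 9 libraries were kept, 10374 in all. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with Benjamini-Hochberg adjustment and a threshold of 0.05, as IL27ra KO minus WT. Single values, such as the level of Il27ra or of a list, were compared with a two-sided exact permutation test over all splits of the 9 libraries into 5 and 4, whose smallest possible p is 0.0159. Before the data were examined, 31 gene lists were fixed, covering interleukin 27 signalling, T cell receptors and effector programs, interferon and STAT3 targets, activation, proliferation, metabolism, stress, and markers of other cells. Of these, 28 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, which asks whether a list moves more than the other genes. With an estimated correlation 0 of the 28 lists passed, the lowest adjusted p being 0.175. Fry, a test of whether a list's genes move on balance 1 way, passed 9 lists. Fixed in the same way was the rule for named genes: 26 genes of interest; the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold, with groups that do not overlap and a group mean of at least 5 FPKM; and up to 4 passing members of each list, by smallest p. Cd244, Lair1, 4632428N05Rik, Gzmm, Pmel, Apoe and the members of gene families in the closing section are named outside that rule and were chosen after their values were seen. Some genes that the rule names are not reported here.

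The tests were tried on simulated values with 200 changed genes among 10374. These took the mean and spread of each gene from these libraries and varied independently between genes. For the comparison of IL27ra KO with WT, changes of 1, 2 and 3 log2 units were recovered for 42%, 92.5% and 96.5% of genes, with 3.45%, 5.61% and 7.21% false calls. A change of 1 log2 unit can therefore go undetected at this number of libraries. With 1 list shifted, 1 list was called. Because the simulated genes varied independently, this does not test the list calls where members are correlated. The estimated correlation was 0.62 for the macrophage list, 0.71 for CD8 T cell identity and 0.89 for ribosomal protein genes.

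The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile, total and median scalings, robust and weighted fits, the replicate number as a block, melanoma or macrophage marker levels as covariates, and each library left out in turn. Scaling to the CD8 T cell identity genes, IL27ra KO replicate 4 alone against WT, and a total without Rn45s were added after the data had been seen. Sex could not be used as a covariate, because all 9 libraries had 38.5 to 79.7 FPKM of Xist and at most 0.11 FPKM of any of 4 Y-linked genes. Lists described one by one in the text were followed through the alternatives as the median of the list relative to that of all genes, and the others through the number of lists that passed.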

Results

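Gene expression was measured by RNA sequencing in CD8+ T cells taken from B16F10 tumours, a transplantable mouse melanoma, in 9 bulk libraries from C57BL/6 mice. The WT group had 5 libraries and the IL27ra KO group, from mice lacking the receptor chain that binds interleukin 27, had 4. The deposited values are TMM-normalized FPKM for 23366 gene symbols, and the number of reads per library is not given with them. The spacing of the low values implied 1750000 to 4100000 fragments per WT library (mean 2780000 ± 960000, SD, n = 5) and 2540000 to 3850000 per IL27ra KO library (mean 3310000 ± 550000, SD, n = 4). Between 13111 and 14358 genes were above 0 in a library. Spearman correlations across genes, which are not independent replicates, were 0.905 to 0.936 within WT, 0.933 to 0.953 within IL27ra KO and 0.903 to 0.933 between the groups, and no 2 libraries were near-identical. The labels do not state that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be in part technical.

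The single comparison of the design asks which genes of CD8+ T cells in the tumour depend on the interleukin 27 receptor. Il27ra itself, the targeted gene, had a mean of 15.3 ± 7.30 FPKM in WT (SD, n = 5) and 6.00 ± 1.56 FPKM in IL27ra KO (SD, n = 4). The 4 IL27ra KO libraries had 4.09, 6.50, 5.62 and 7.80 FPKM. The libraries labelled WT replicates 1, 3, 4 and 5 had 25.7, 15.2, 14.4 and 15.8 FPKM, whereas the library labelled WT replicate 2 had 5.14 FPKM, inside the IL27ra KO range. The difference was -1.10 on the log2 scale (SE 0.34) and did not pass (limma, adjusted p = 0.0996; two-sided exact permutation p = 0.0635). Without the library labelled WT replicate 2 the difference was -1.42 and passed (limma, adjusted p = 0.0035), and it also passed with weights for library quality (-1.42, adjusted p = 0.0012). The labels do not say which part of the gene was disrupted, and a gene-level value sums over the whole transcript.

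IL27ra KO libraries had less RNA for some inhibitory and activating receptors of T cells, 7 of 24 and 5 of 15 tested, and more RNA for all 21 tested genes of macrophages and monocytes than WT libraries. Lag3, an inhibitory receptor, fell from 46.2 ± 31.3 FPKM (SD, n = 5) to 2.52 ± 0.72 FPKM (SD, n = 4), and Pdcd1, which encodes PD-1, fell from 94.9 ± 45.8 to 8.32 ± 3.93 FPKM. Lyz2, a lysozyme of macrophages and neutrophils, rose from 36.0 ± 31.1 to 429 ± 173 FPKM. Of 10374 genes tested, 440 changed (limma, adjusted p under 0.05), 325 of them higher and 115 lower in IL27ra KO. Of these, 381 changed by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. The values of the groups did not overlap for 349 of the 440, and for 6.73% of all genes tested against 1.59% by chance. Among genes of at least 5 FPKM in a group whose groups did not overlap, the largest rises were those of Ccl7 (log2 change 3.93), Ccl6 (3.92), Lyz2 (3.87), Lyz1 (3.75), Cxcl2 (3.56), Thbs1 (3.53), Ccl2 (3.49) and Csf1r (3.48), which encode chemokines, lysozymes, thrombospondin 1 and the receptor for colony-stimulating factor 1. The largest falls among them were those of Lag3 (-3.52), Penk (-3.48), Pdcd1 (-3.36), Tnfrsf4 (-3.17), Serpina3g (-3.10), Rgs16 (-3.07), Tnfrsf9 (-2.87) and Serpine2 (-2.84), and the adjusted p of these 16 genes was at most 0.0087. The Ccl2 call was lost with a pseudocount of 0.1 and with the robust fit. Lyz1 and Lyz2 share sequence, so their separate values are uncertain.

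The split between higher and lower calls moved with the scaling of the libraries. Against 325 higher and 115 lower, quantile normalization gave 291 and 167, rescaling each library to the same total gave 474 and 62, and scaling to the CD8 T cell identity genes gave 579 and 50. The last 2 scalings moved the median change of all genes by 0.32 and 0.46 log2 units, and all 440 genes kept their direction under each of the 3. Scaling to the CD8 T cell identity genes ended the calls of 15 named genes that were lower, Entpd1, Prdm1, Stat3, Crtam, Tnfrsf1b, Ikzf2, Nr4a2, Cst7, Ccl3, Xcl1, Ccr8, Gbp6, Chac1, Cd3e and Cd8a (adjusted p = 0.0568 to 0.481), and rescaling to the same total ended 14 of these, all but that of Ikzf2. The count fell to 242, 268 and 226 without IL27ra KO replicates 1, 2 and 3, to 219 among genes of at least 5 FPKM, and to 0 with the macrophage marker level as a covariate (limma; 963 genes at an unadjusted p under 0.05), and it rose to 974 with weights for library quality. Lower calls numbered 70 without WT replicate 5 and 184 without IL27ra KO replicate 4. IL27ra KO replicate 4 alone, set against WT after its marker levels were seen, gave 2 genes.

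Macrophage and monocyte genes rose together in the IL27ra KO libraries. All 21 members tested were higher, over all genes and when adjusted over the list alone, with a median log2 change of 2.87 (camera, adjusted p = 3.3e-32; adjusted p = 0.175 with an estimated correlation). Fewer passed in some other fits: 16, 16 and 15 without IL27ra KO replicates 1, 2 and 3, and 15 with the robust fit. The melanoma covariate left 18, as did leaving out WT replicate 3, and with no filter 16 of 22 passed. Csf1r rose from 2.02 ± 1.60 to 33.1 ± 17.5 FPKM, Mrc1, the mannose receptor, from 0.872 ± 0.645 to 18.2 ± 11.3 FPKM, and Trem2 from 0.532 ± 0.457 to 7.15 ± 1.22 FPKM (SD, n = 5 and n = 4; adjusted p = 0.0010, 0.00047 and 0.00036). Emr1, which encodes F4/80, and Ms4a7 rose by 3.08 and 2.83 log2 units. The mean log2 level of the list was 5.28, 5.07, 5.55 and 3.88 in IL27ra KO replicates 1 to 4 and 1.41, 2.79, 1.43, 2.25 and 2.77 in WT replicates 1 to 5. Of 8 dendritic cell genes, 5 rose and 3 did not pass. In all, 7 were higher when adjusted over the list alone (median 2.81, camera adjusted p = 4.4e-06; adjusted p = 0.175 with an estimated correlation). Cd74, the invariant chain of MHC class II, rose from 65.1 ± 64.6 to 515 ± 270 FPKM and the class II gene H2-Ab1 from 54.3 ± 58.6 to 421 ± 216 FPKM, and the library labelled WT replicate 2 had 165 and 145 FPKM of these genes. Itgax rose by 1.84 and Cd209a by 2.34 log2 units. The Cd74 and Cd209a calls were lost without IL27ra KO replicate 1, 2 or 3 (highest adjusted p = 0.0644 and 0.0673), and that of H2-Ab1 without these or WT replicate 1 or 3 (highest adjusted p = 0.105). Of 4 neutrophil genes, Il1b (log2 change 2.89) and Clec4d (1.58) rose and 2 did not pass. In all, 3 were higher when adjusted over the list alone (median 1.30, camera adjusted p = 0.0020; adjusted p = 0.204 with an estimated correlation). The filter left 4 of 12 neutrophil and 8 of 16 dendritic cell genes, and with no filter the list medians relative to all genes went from 1.27 and 2.78 to 0.12 and 0.89, while pseudocounts of 5 and 0.1 gave 0.49 and 2.50 for neutrophil genes. The Il1b call was lost without IL27ra KO replicate 3 (adjusted p = 0.0600), and the Clec4d call in 7 of the 9 fits that left out 1 library (highest adjusted p = 0.179, without IL27ra KO replicate 3). The neutrophil list did not pass with the macrophage covariate (median relative to all genes 0.17, camera adjusted p = 0.973). Which cells made the RNA of the dendritic cell and neutrophil lists was not tested.

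**Figure D1:**
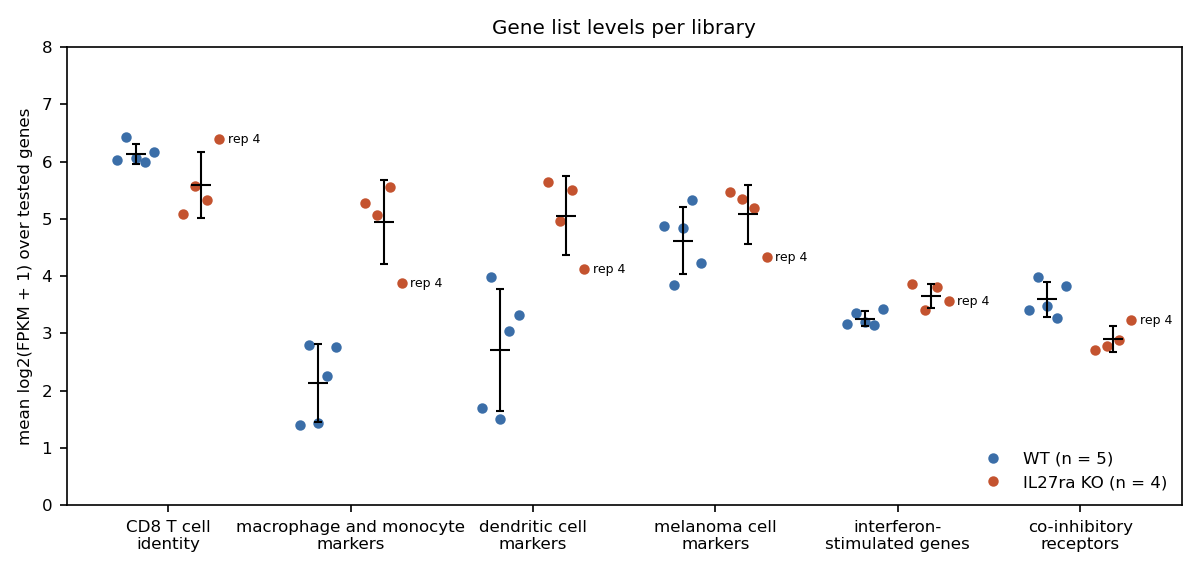
Mean log2(FPKM + 1) over the tested genes of 6 gene lists, in each of the 5 WT libraries (blue) and 4 IL27ra KO libraries (red). Black bars mark the mean ± SD of a group, and IL27ra KO replicate 4 is marked. Macrophage marker levels lay between 3.88 and 5.55 in the IL27ra KO libraries and between 1.41 and 2.79 in WT.

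Genes of CD8 T cell identity passed as lower as a list. The median log2 change of the 15 members was -0.57 (camera, adjusted p = 1.2e-05; adjusted p = 0.375 with an estimated correlation; fry, adjusted p = 0.192), with 2 lower and 13 not past the threshold over all genes, and 7 lower and 1 higher when adjusted over the list alone. Without IL27ra KO replicate 4, 8 members were lower over all genes (median -0.88), and without IL27ra KO replicate 1, 0 were (median -0.37). With the macrophage covariate, a level that runs with the genotype, the list did not pass (camera, adjusted p = 0.671). Its median relative to all genes went from -0.59 to -0.01 there. Cd3e, a chain of the T cell receptor complex, fell from 222 ± 50.2 to 102 ± 50.3 FPKM and Cd8a from 88.4 ± 23.7 to 41.3 ± 20.2 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0317 and 0.0421). Both calls were lost in most of the fits that left out 1 library, 6 of 9 for Cd3e and 7 of 9 for Cd8a (highest adjusted p = 0.143 and 0.174, without IL27ra KO replicate 1). The mean log2 level of the list was 6.14 ± 0.17 in WT and 5.08, 5.57, 5.32 and 6.39 in IL27ra KO replicates 1 to 4, so that replicate 4 lay above the WT mean (two-sided exact permutation p = 0.0794 for the group means). Of 17 melanoma genes, 16 did not pass and Kit, a receptor tyrosine kinase of melanocytes and mast cells, fell from 4.64 ± 1.45 to 0.71 ± 0.46 FPKM, with the same count when adjusted over the list alone. The melanoma list passed as higher with a median of 0.55 (camera, adjusted p = 0.0161; adjusted p = 0.701 with an estimated correlation; fry, adjusted p = 0.498), and the pigment gene Pmel had means of 188 and 262 FPKM in WT and IL27ra KO. That call was lost without WT replicate 2 or 5 or IL27ra KO replicate 1 or 2 (highest adjusted p = 0.111), on rescaling to the same total (adjusted p = 0.0506) and on scaling to the CD8 T cell identity genes (adjusted p = 0.136). Of 18 stromal genes, 3 were tested. Among these, Fn1, which encodes fibronectin, rose from 3.32 ± 1.47 to 40.3 ± 26.0 FPKM and 2 did not pass, with the same count when adjusted over the list alone. The stromal list passed with a median of 0.47 (camera, adjusted p = 0.0250; adjusted p = 0.243 with an estimated correlation), and not without WT replicate 2 or 5 (highest adjusted p = 0.0921), with no filter (adjusted p = 0.355) or with the melanoma covariate (adjusted p = 0.0915).

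The co-inhibitory receptors passed as lower as a list, with large falls of some members. Of 24 members tested, 7 fell (Pdcd1, Havcr2, Lag3, Tigit, Ctla4, Cd244 and Entpd1), 2 rose and 15 did not pass. In all, 12 were lower and 3 higher when adjusted over the list alone. Their median log2 change was -0.67 (camera, adjusted p = 4.4e-06; adjusted p = 0.204 with an estimated correlation). Havcr2, which encodes TIM-3, fell from 25.7 ± 14.7 to 3.38 ± 1.00 FPKM, Tigit from 150.5 ± 79.7 to 26.9 ± 13.3 FPKM, and Ctla4 from 77.7 ± 28.5 to 21.3 ± 5.32 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0014, 0.0025 and 0.0025). Lag3 and Pdcd1 were 18.3 and 11.4 times as high in WT as in IL27ra KO (log2 SE 0.38 and 0.38, adjusted p = 0.00047 and 0.00048). Entpd1, the ectonucleotidase CD39, fell by 0.99 log2 units, and its call was lost in 6 of 9 fits that left out 1 library (highest adjusted p = 0.118, without IL27ra KO replicate 1). The members that rose were Lair1 (log2 change 1.62) and 4632428N05Rik (0.73), which encodes VISTA. Both receptors are also made by myeloid cells. Without IL27ra KO replicate 1, 2 or 3, 1 member passed as higher, as with the replicate block and the filter at 5 FPKM. Pdpn, which encodes podoplanin, had 2.18 ± 0.91 FPKM in WT and 3.67 ± 1.43 FPKM in IL27ra KO (adjusted p = 0.432), and Procr, the protein C receptor, with 0.836 and 0.72 FPKM, was too low to be tested. The mean log2 level of the 7 receptors that fell was 5.12 ± 0.60 in WT and 2.87 ± 0.21 in IL27ra KO, a difference of -2.25, beside one of -0.55 for the CD8 T cell identity list and 2.82 for the macrophage list. In IL27ra KO replicate 4 the corresponding differences from the WT mean were -2.01, 0.25 and 1.76. The 7 receptors were picked for their fall. The whole list had a median relative to all genes of -0.16 in IL27ra KO replicate 4 alone, against -0.69 over all 4 libraries. After scaling to the CD8 T cell identity genes, 5 of the 7 receptors were past the threshold, and the median of the 24 was -0.22, with 5 lower and 3 higher. With the macrophage marker level as a covariate none of the 7 was past the threshold and all 7 were below 0, with wider errors: Pdcd1 went from -3.36 (SE 0.38) to -3.80 (SE 0.94), Havcr2 from -2.46 (SE 0.34) to -3.22 (SE 0.83) and Tigit from -2.41 (SE 0.38) to -2.26 (SE 0.95).

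**Figure D2:**
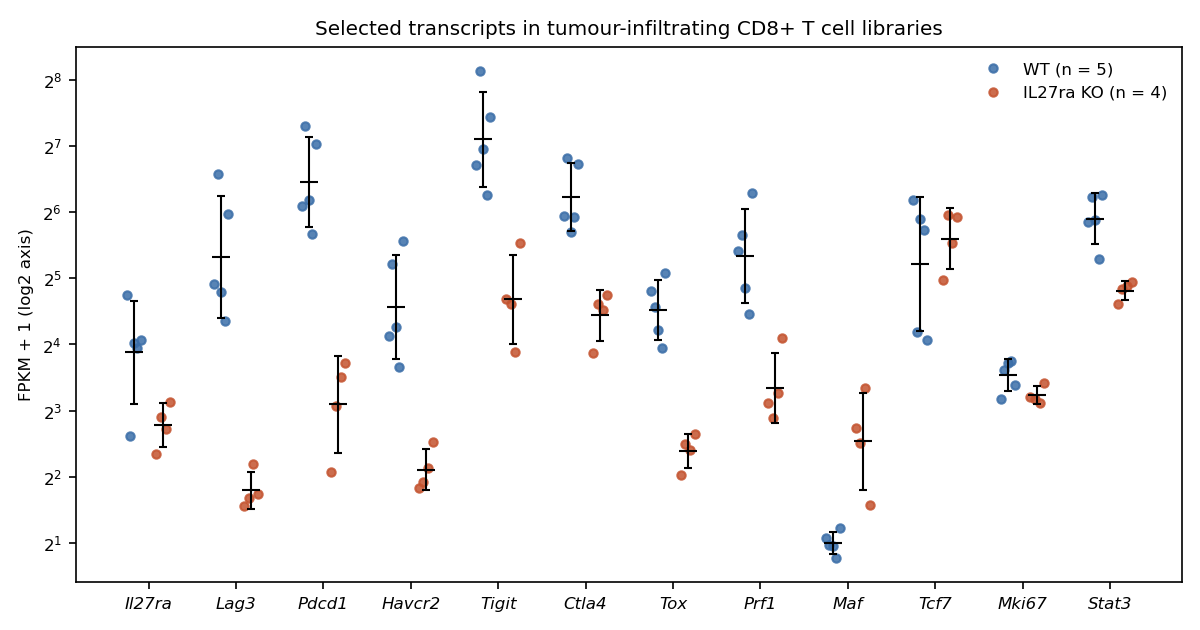
FPKM + 1 on a log2 axis for 12 transcripts in each of the 5 WT libraries (blue) and 4 IL27ra KO libraries (red). Black bars mark the mean ± SD of log2(FPKM + 1) in a group. The Lag3 values lie between 1.96 and 3.57 FPKM in IL27ra KO and between 19.4 and 94.1 FPKM in WT.

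The lists of co-stimulatory receptors and of regulators of exhaustion passed as lower as well. Of 15 co-stimulatory genes, 5 fell, 1 rose and 9 did not pass. In all, 7 were lower and 1 higher when adjusted over the list alone (median -0.72, camera adjusted p = 1.7e-05; adjusted p = 0.243 with an estimated correlation). Tnfrsf4, which encodes OX40, fell from 31.8 ± 25.3 to 1.92 ± 0.79 FPKM, and Tnfrsf9, which encodes 4-1BB, from 56.7 ± 29.2 to 6.46 ± 2.66 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0019 and 0.0011). Crtam and Tnfrsf1b fell by 1.26 and 0.81 log2 units and Cd40lg, the CD40 ligand, rose by 0.98, and these calls were lost in 3, 5 and 7 of 9 fits that left out 1 library (highest adjusted p = 0.0898, 0.112 and 0.161). Of 20 regulators, 6 fell, 2 rose and 12 did not pass. In all, 8 were lower and 2 higher when adjusted over the list alone (median -0.62, camera adjusted p = 3.5e-05; adjusted p = 0.204 with an estimated correlation). Tox, a DNA-binding protein of exhausted T cells, fell from 22.9 ± 7.39 to 4.31 ± 0.91 FPKM, and Ikzf2, which encodes Helios, from 5.92 ± 2.96 to 1.36 ± 0.24 FPKM (adjusted p = 0.00048 and 0.0085). On scaling to the CD8 T cell identity genes Tox passed (log2 change -1.65, adjusted p = 0.0013) and Ikzf2 did not (-1.05, adjusted p = 0.0712). Prdm1, which encodes Blimp-1, fell from 10.6 ± 4.06 to 3.55 ± 0.97 FPKM and Nr4a2 from 23.1 ± 8.21 to 8.63 ± 1.77 FPKM, and both calls were lost without IL27ra KO replicate 1 (adjusted p = 0.0712 and 0.0582). Maf, the transcription factor c-MAF, rose from 1.01 ± 0.23 to 5.36 ± 2.95 FPKM (adjusted p = 0.0081). Its IL27ra KO values were 5.64, 4.68, 9.12 and 1.98 FPKM, in replicates whose macrophage levels were 5.28, 5.07, 5.55 and 3.88. In IL27ra KO replicate 4 alone neither list passed, with medians relative to all genes of 0.20 and -0.20 (adjusted p = 0.533 and 0.0995), nor did they with the macrophage covariate (adjusted p = 0.541 and 0.363). Tbx21 and Eomes, the T-box factors of effector cells, differed by -0.63 and -0.75 log2 units and did not pass (adjusted p = 0.378 and 0.299).

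**Figure D3:**
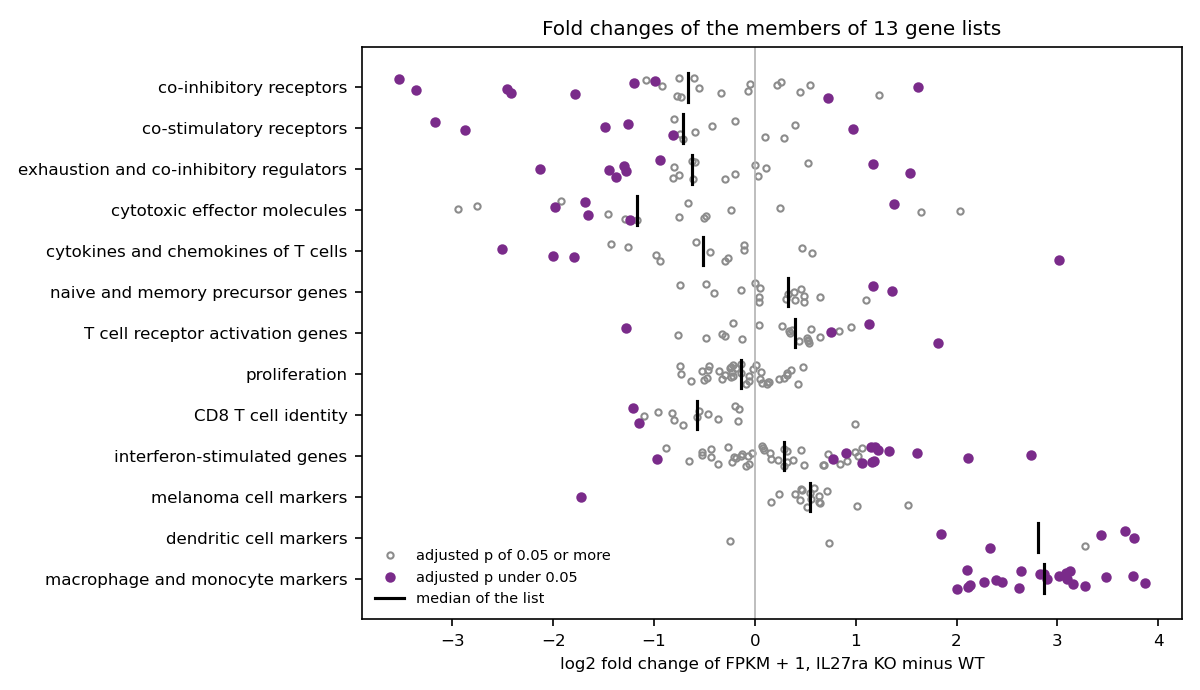
Log2 fold changes of FPKM + 1, IL27ra KO minus WT, for the tested members of 13 gene lists. Filled purple points had an adjusted p under 0.05 over all genes, open grey points did not, and black bars mark the median of a list, -0.67 for co-inhibitory receptors and 2.87 for macrophage and monocyte markers.

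The lists of cytotoxic genes and of T cell cytokines and chemokines passed as lower with camera, and most of their members did not pass. Of 19 cytotoxic genes, 4 fell, 1 rose and 14 did not pass. In all, 11 were lower and 3 higher when adjusted over the list alone (median -1.17, camera adjusted p = 1.2e-05; adjusted p = 0.375 with an estimated correlation). Prf1, the pore-forming protein perforin, fell from 43.3 ± 21.9 to 9.71 ± 4.36 FPKM, and Serpinb9, an inhibitor of granzyme B, from 33.2 ± 18.8 to 8.61 ± 2.35 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0047 and 0.0117). Serpinb6b and Cst7 fell by 1.65 and 1.24 log2 units. Their calls were lost without IL27ra KO replicate 3 (adjusted p = 0.0524) and in 6 of 9 fits that left out 1 library (highest adjusted p = 0.165), respectively. Gzmm, with 0.744 and 4.25 FPKM, was the member that rose (log2 change 1.38). Gzmb had 152 ± 121 FPKM in WT and 54.5 ± 31.0 FPKM in IL27ra KO and did not pass (adjusted p = 0.194), and granzyme genes share sequence, so their separate values are uncertain. Of 16 cytokine and chemokine genes, 3 fell, 1 rose and 12 did not pass. In all, 5 were lower and 1 higher when adjusted over the list alone (median -0.51, camera adjusted p = 0.0020; adjusted p = 0.375 with an estimated correlation). Ccl1, Xcl1 and Ccl3 fell by 2.51, 2.00 and 1.79 log2 units and Ccl9, a chemokine of myeloid cells, rose by 3.01. The calls of Ccl1, Xcl1, Ccl3 and Ccl9 were lost in 7, 8, 7 and 3 of 9 fits that left out 1 library (highest adjusted p = 0.151, 0.136, 0.0996 and 0.0703). Ifng, the gene of interferon gamma, had 30.4 ± 18.9 FPKM in WT and 16.4 ± 15.0 FPKM in IL27ra KO (adjusted p = 0.341), with 38.9 FPKM in IL27ra KO replicate 4, and passed as lower without that library (log2 change -1.49, adjusted p = 0.0389). By fry neither list passed (adjusted p = 0.192 and 0.284). In IL27ra KO replicate 4 alone, whose CD8 T cell identity level was 0.25 above the WT mean, neither passed, with medians relative to all genes of -0.29 and -0.18 (adjusted p = 0.746 and 0.703) against -1.19 and -0.53 over all 4 libraries. The cytokine call was also lost with the filter at 5 FPKM (adjusted p = 0.0688) and the melanoma covariate (adjusted p = 0.184). With that covariate the cytotoxic median relative to all genes went from -1.19 to -0.58. Co-inhibitory and co-stimulatory receptors went from -0.69 to -0.45 and from -0.74 to -0.44. Exhaustion regulators and CD8 T cell identity went from -0.64 and -0.59 to -0.33 each. All of these lists still passed (camera, highest adjusted p = 0.00038). Tnf and Il10 had log2 changes of 0.47 and -0.58 (adjusted p = 0.344 and 0.524).

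The interferon-stimulated genes passed as higher as a list, through a minority of its members. Of 51 members tested, 12 rose, 1 fell and 38 did not pass. In all, 20 were higher and 2 lower when adjusted over the list alone (median 0.29, camera adjusted p = 0.0003; adjusted p = 0.375 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, rose from 0.578 ± 0.389 to 9.79 ± 3.73 FPKM, and Usp18, a protease that removes ISG15, from 1.40 ± 0.51 to 6.58 ± 3.15 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.00036 and 0.0029). Irf7 rose by 1.33 log2 units and Gbp6, a guanylate-binding protein induced by interferon gamma, fell by 0.97. The Gbp6 call was lost without IL27ra KO replicate 1 (adjusted p = 0.0514) and the Irf7 call without IL27ra KO replicate 1 or 3 (highest adjusted p = 0.0626). The members that passed as higher numbered 7 without WT replicate 1, 3 without IL27ra KO replicate 1 and 2 without IL27ra KO replicate 3. They numbered 16 on rescaling to the same total and 21 on scaling to the CD8 T cell identity genes (median 0.76), with 0 lower under both. The Oas genes share sequence, so their separate values are uncertain. The mean log2 level of the 12 members that rose was 1.37 higher in IL27ra KO, in libraries whose macrophage level was 2.82 higher.

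Genes of signalling downstream of the receptor changed in part. Of the 10 genes of interleukin 27 reception and signalling, Stat3 fell from 60.4 ± 15.2 to 27.2 ± 2.74 FPKM (limma, adjusted p = 0.0116) and 9 did not pass. In all, 2 were lower and 1 higher when adjusted over the list alone. The Stat3 call was lost without IL27ra KO replicate 1 (adjusted p = 0.0572) and on scaling to the CD8 T cell identity genes, where its log2 change went from -1.09 to -0.55 (adjusted p = 0.229). Socs3, a feedback inhibitor of STAT3 signalling, had 32.7 ± 14.3 and 60.8 ± 6.63 FPKM (adjusted p = 0.10). The list did not pass (median -0.14, camera adjusted p = 0.270). It passed as lower without the library labelled WT replicate 2 (median relative to all genes -0.22, adjusted p = 0.0434) and with quality weights (-0.31, adjusted p = 0.0494), and as higher with the macrophage covariate (0.50, adjusted p = 0.0498). Nor did the STAT3 target genes pass as a list (median 0.23, adjusted p = 0.249), of which Fos rose and 16 did not pass. In all, 4 of these targets were higher and 1 lower when adjusted over the list alone. Of 19 naive and memory precursor genes, Il6ra and Klf2 rose and 17 did not pass. In all, 2 were higher and 1 lower when adjusted over the list alone (median 0.33, camera adjusted p = 0.175). That list passed as higher without WT replicate 4 or IL27ra KO replicate 1 (adjusted p = 0.0494 and 0.0209), in IL27ra KO replicate 4 alone (median relative to all genes 0.63, adjusted p = 0.0010) and with the macrophage covariate (1.26, adjusted p = 7.3e-10). Its median relative to all genes went from 0.31 to 0.11 without WT replicate 2 or 5 (adjusted p = 0.483 and 0.784), to 0.15 without IL27ra KO replicate 4 (adjusted p = 0.668) and to 0.05 with the melanoma covariate (adjusted p = 0.588). Il6ra, a chain of the interleukin 6 receptor, rose from 4.09 ± 1.49 to 11.7 ± 2.12 FPKM, and Klf2, a transcription factor of T cell recirculation, from 10.01 ± 2.95 to 23.5 ± 4.72 FPKM (SD, n = 5 and n = 4; adjusted p = 0.0045 and 0.0077). Tcf7, Slamf6 and Il7r, genes of memory precursors, had log2 changes of 0.38, -0.49 and 0.31 (adjusted p = 0.754, 0.579 and 0.672). Of 24 genes of T cell receptor activation, Fos, Fosb and Atf3 rose by 1.14, 0.75 and 1.81 log2 units, Nr4a2 fell and 20 did not pass. In all, 3 were higher and 2 lower when adjusted over the list alone (median 0.40, camera adjusted p = 0.0576). Atf3 had 44.9, 22.8, 39.8 and 11.5 FPKM in IL27ra KO replicates 1 to 4, whose macrophage levels were 5.28, 5.07, 5.55 and 3.88. With the macrophage covariate the log2 changes of Fos, Fosb and Atf3 were 0.93, 0.51 and -0.07, and none of these passed. The Fos and Atf3 calls were lost without IL27ra KO replicate 1 or 3 (highest adjusted p = 0.0634 and 0.0559) and that of Fosb in 5 of 9 fits (highest adjusted p = 0.127), and the list passed without WT replicate 2 or 3 or IL27ra KO replicate 1 or 2 (lowest adjusted p = 0.0275) and in 8 of 15 other settings. No gene of the 38 in the proliferation list passed, over all genes or when adjusted over the list alone (median -0.14, camera adjusted p = 0.0576), and Mki67, which encodes Ki-67, had 10.7 ± 1.88 and 8.42 ± 0.91 FPKM (adjusted p = 0.503). The proliferation list passed as lower without WT replicate 1 or 2 or IL27ra KO replicate 2 (lowest adjusted p = 0.0084) and in 3 of 15 other settings.

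Among migration genes, Ccr2, a chemokine receptor of monocytes and effector T cells, rose from 8.44 ± 4.44 to 37.9 ± 11.9 FPKM, while Rgs16 and Ccr8 had log2 changes of -3.07 and -1.20 and fell (SD, n = 5 and n = 4; limma, adjusted p = 0.0020, 0.00056 and 0.0045). On scaling to the CD8 T cell identity genes Rgs16 was at -2.54 and Ccr8 at -0.75, where its call was lost (adjusted p = 0.133). The other 17 members did not pass. In all, 1 was higher and 3 lower when adjusted over the list alone (median -0.04, camera adjusted p = 0.585). Of 20 genes of apoptosis and survival, 1 fell and 19 did not pass. In all, 1 was higher and 3 lower when adjusted over that list alone (median -0.07, camera adjusted p = 0.103). Of 19 stress genes, Hspb1 and Chac1 fell by 1.41 and 0.98 log2 units, 17 did not pass, and the count was the same when adjusted over the list alone (median -0.15, camera adjusted p = 0.265). The Hspb1 and Chac1 calls were lost in 4 and 6 of 9 fits that left out 1 library (highest adjusted p = 0.0675 and 0.105). Of 10 NK cell genes, Tyrobp, Fcer1g and Fcgr3 rose by 3.01, 2.42 and 3.11 log2 units and 7 did not pass. In all, 3 were higher and 1 lower when adjusted over the list alone. These 3 genes encode Fc receptor and adaptor chains that myeloid cells also make, the median of the list was -0.15 and its mean 0.49, and it did not pass (camera, adjusted p = 0.748). Of 7 genes of CD4 and regulatory T cells, Cd40lg rose and 6 did not pass. In all, 2 were higher and 2 lower when adjusted over the list alone; the median was 0.10, the mean -0.06 and camera's direction down (adjusted p = 0.748). No member passed, over all genes or when adjusted over the list alone, among 23 genes of glycolysis, 39 of oxidative phosphorylation, 21 of sterol synthesis, 3 metallothionein and zinc genes and 3 erythroid genes. Their camera adjusted p was 0.585, 0.876, 0.484, 0.484 and 0.708, and for oxidative phosphorylation the median was 0.07 while camera's direction was down. The 80 ribosomal protein genes passed as lower with a median of -0.19 (camera, adjusted p = 0.0020; adjusted p = 0.808 with an estimated correlation; fry, adjusted p = 0.708) and with no member past the threshold, over all genes or when adjusted over the list alone. That call was lost without IL27ra KO replicate 1 (adjusted p = 0.0706) and without WT replicate 2, where the median relative to all genes was 0.03 (adjusted p = 0.483). It was also lost, from -0.21, under quantile normalization (-0.04, adjusted p = 0.0732), quality weights (-0.08, adjusted p = 0.151) and scaling to the CD8 T cell identity genes (-0.12, adjusted p = 0.261). The members with the smallest p were Rps27 and Rps15a, with log2 changes of -3.22 and -0.41 (adjusted p = 0.149 and 0.570); Rps27 had 13.9, 1119, 321 and 9.37 FPKM in IL27ra KO replicates 1 to 4 and has near-identical copies, so its value is uncertain. B cell, sex-linked and mitochondrially encoded genes had fewer than 3 tested members and were not tested as lists.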

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

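Each named gene and each list level was searched within a group for a library whose gap to its nearest neighbour took most of the group's range. Of 222 groups of values, 16 held such a library, where chance at 1 in 20 gives 11.1, so the number itself is close to chance.

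IL27ra KO replicate 4 stood above the other 3 IL27ra KO libraries in 4 values. It had 20.98 FPKM of Tbx21, a transcription factor of effector T cells (next highest 9.09), 38.9 FPKM of Ifng (next highest 10.3) and 12.1 FPKM of Serpinb9 (next highest 7.75). Its mean log2 level of the tissue residency and migration genes was 5.00 (next highest 4.50). IL27ra KO replicate 1 had 2.02 FPKM of Penk (next highest 0.21) and 11.3 FPKM of Usp18 (next highest 5.62).

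The library labelled WT replicate 2 stood apart from the other WT libraries in 5 values. It had 284 FPKM of the chemokine gene Ccl3 (next highest 103), 13.4 FPKM of Atf3 (next highest 7.01), 58.2 FPKM of Fcer1g (next highest 22.1) and 108 FPKM of Rps15a (next highest 49.4), and the lowest mean log2 level of the sterol synthesis genes, 2.95 (next lowest 3.42). WT replicate 5 had the highest Emr1, Ms4a7 and Kit, at 2.09, 2.09 and 7.21 FPKM (next highest 0.41, 0.34 and 4.25). WT replicate 4 had 3.97 FPKM of Thbs1 (next highest 0.98), and WT replicate 3 the lowest Fosb, 13.3 FPKM (next lowest 16.7).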

How the results depend on the processing

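The alternatives marked as added in the methods (scaling to the CD8 T cell identity genes, IL27ra KO replicate 4 alone, and a total without Rn45s) were chosen after the data had been seen, and the cause of a change was not tested unless given here. Counts of changed genes are given against 440 (325 higher, 115 lower). Depth limits genes near 1 FPKM, where 1 fragment in 1 kb is worth 0.244 to 0.572 FPKM. With a filter at 5 FPKM, which tested fewer genes, 219 changed (155 higher, 64 lower). Quality weights gave 974 (632 higher, 342 lower). Rescaling to the same total gave 62 lower genes, the melanoma covariate 76 lower, and scaling to the CD8 T cell identity genes 579 higher and 50 lower. IL27ra KO replicate 4 alone, 1 library assumed to vary like the others, gave 2 genes, 1 higher and 1 lower. With the macrophage covariate 0 genes passed, 0 higher and 0 lower, with 963 at an unadjusted p under 0.05. That covariate had r = 0.913 with the genotype and inflated the variance of the difference 6.14 times. Both pseudocounts, no filter, quantile and median scaling, the robust fit and the total without Rn45s left each count within 1.5 times.

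Leaving out each library in turn gave 226 to 632 changed genes, 169 to 448 higher and 57 to 184 lower, with all 440 in the same direction each time. Of the 67 named genes that passed, 40 passed in all 9 of these fits, as did 10 of the 13 lists. The number of lists ranged from 11 to 14 against 13, and was 0 with an estimated correlation. The Il27ra difference ranged from -1.42 to -0.88, with adjusted p = 0.0035 without the library labelled WT replicate 2. It was -1.42 with quality weights (limma, adjusted p = 0.0012), and over all alternatives its adjusted p ranged from 0.0012 to 0.999. The ribosomal protein list, relative to all genes, ranged from -0.31 to 0.0302, the last without WT replicate 2.

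No pairing of the libraries by the replicate numbers 1 to 4 was detected. Same-numbered libraries had correlations of deviations of 0.003, -0.008, -0.07 and -0.15, and none of the IL27ra KO libraries matched its own number best. With so few libraries this cannot show that the numbers mark no day or batch, which the labels do not state. With the replicate number as a block and WT replicate 5 left out, 273 genes changed, 217 higher and 56 lower, and the melanoma and stromal lists did not pass (camera, adjusted p = 0.0984 and 0.0583).

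Directions turned as follows, on the log2 scale. Rescaling to the same total gave 0.0016 for Mki67. With the macrophage covariate Il27ra was at 0.51, Slamf6 at 1.31, Tbx21 at 0.0742, Tnf at -0.0046 and Cd3e at 0.0381. In the same fit Ccl7, Ccl6, Lyz2, Cxcl2 and Ccl2 were at -0.0915, -0.40, -0.29, -0.72 and -1.20, Ccl9 and Atf3 at -1.86 and -0.0724, Fcgr3, Fcer1g and Tyrobp at -1.13, -0.72 and -1.37, and Cd74, Cd209a, H2-Ab1 and Il1b at -2.21, -1.27, -2.94 and -1.17. None of these passed there, and a covariate built from macrophage genes removes their own change by construction. Scaling to the CD8 T cell identity genes gave 0.0178 for Slamf6, 0.20 for Mki67 and 0.13 for Rps15a, beside a shift of 0.46 in the median of all genes. IL27ra KO replicate 4 alone gave 0.37 for Tbx21 and 0.53 for Ifng. For lists, relative to all genes, the macrophage covariate gave 0.50 for interleukin 27 signalling, -0.12 for interferon-stimulated, -0.0707 for macrophage and -1.79 for dendritic cell genes, of which the first passed as higher and the last as lower (adjusted p = 0.0498 and 0.0295). IL27ra KO replicate 4 alone gave 0.21 for interleukin 27 signalling, 0.20 for co-stimulatory receptors, 0.25 for CD8 T cell identity, -0.33 for melanoma and 0.0179 for ribosomal protein genes, and of these the melanoma list passed as lower (adjusted p = 0.0398). The melanoma covariate gave 0.0605 for ribosomal protein genes, and no filter gave -0.0081 for stromal genes.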

Other observations

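The tests of the splits of the libraries, of the slope of the interferon-stimulated genes and of 3 of the 5 scalings were set before their results were seen. Scaling to the CD8 T cell identity genes, the total without Rn45s, all other tests here and the gene families were chosen after. In 7 families of genes of innate immunity, antigen presentation and proteolysis, picked for their changed members and not tested for enrichment, 46 genes were higher in IL27ra KO, of which 11 are also in the fixed lists. Of 14 C-type lectin genes tested, 10 rose and 0 fell, and Clec4n, which encodes dectin-2, went from 0.946 ± 1.05 to 16.5 ± 11.4 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0015). Of 7 Toll-like receptor genes 6 rose, of 4 Fc gamma receptor genes 4, of 9 complement genes 8, of 7 Ms4a genes 5 and of 11 cathepsin genes 6, and no member of these families fell. Cfp, the complement factor properdin, rose from 3.10 ± 2.31 to 37.9 ± 18.8 FPKM and Tlr2 from 1.03 ± 0.51 to 6.26 ± 3.13 FPKM (adjusted p = 0.0012 and 0.0062). Of 10 genes of MHC class II 7 rose, among them the transactivator gene Ciita, from 0.348 ± 0.314 to 3.19 ± 2.00 FPKM (adjusted p = 0.0196). Under 5 other scalings at least 7 lectin, 5 Toll-like receptor, 4 Fc gamma receptor, 7 complement, 5 Ms4a and 6 cathepsin genes rose, and 0 fell.

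In the serpin family of protease inhibitors the changed members were lower. Of 10 serpin genes tested, 6 fell and 0 rose, and under 5 other scalings at least 5 fell and 0 rose. Serpina3g fell from 63.0 ± 45.4 to 5.30 ± 1.85 FPKM, Serpinb9b from 11.2 ± 11.9 to 0.43 ± 0.53 FPKM and Serpine2 from 10.5 ± 9.83 to 0.16 ± 0.24 FPKM (SD, n = 5 and n = 4; limma, adjusted p = 0.0013, 0.0090 and 0.0087). Several mouse serpins are near-identical copies, so their separate values are uncertain. Of 13 genes of the TNF receptor superfamily, Tnfrsf4, Tnfrsf9, Tnfrsf18 and Tnfrsf1b fell and Tnfrsf21 rose from 0.366 ± 0.247 to 3.12 ± 1.03 FPKM (adjusted p = 0.0024). When libraries were rescaled to the same total or to the CD8 T cell identity genes, 2 of these 4 passed as lower, Tnfrsf4 and Tnfrsf9, and 3 members of the family as higher.

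The 440 changed genes are more than other splits of the libraries give. Of 100 splits of the 9 libraries into 5 and 4, drawn with the real split among them, 1 gave as many genes, the real split itself. The highest of the others gave 120. Chance alone is therefore excluded as the source of the count only if the libraries are independent, which the labels do not state.

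Myeloid genes were higher in the IL27ra KO libraries, although the labels describe isolated CD8+ T cells, a step that should remove most myeloid cells. A scaling effect is excluded, since at least 20 of the 21 macrophage markers passed as higher under each of 5 scalings, and a smaller share of T cells that raises all other cells alike is excluded, since the macrophage level rose by 2.36 ± 0.54 (SE) log2 units more than the melanoma level (two-sided exact permutation p = 0.0159, the smallest the design allows). RNA of myeloid cells is a candidate explanation, and a joint rise of all 21 tested markers is what it would give. The abundant markers Lyz2 and Apoe had 429 and 394 FPKM in IL27ra KO. The slope test could not decide it, as it asks whether T cell RNA is diluted and not whether myeloid RNA is present. The slope of CD8 T cell identity on macrophage level within the groups was -0.25 ± 0.20 (SE) (two-sided exact permutation p = 0.313). Of the 21, 1 is also in another list and 15 had at least 1 FPKM in WT. Whether more myeloid cells in tumours of mice without the receptor, or a less clean isolation, would be the source stays open, as the design has no measure of either.

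Several co-inhibitory receptors were lower in the IL27ra KO libraries, of which replicates 1 to 3 also had lower levels of CD8 T cell identity genes than any WT library and replicate 4 did not. The 7 tested receptors among the genes of interest were fixed before the data were examined: Pdcd1, Havcr2, Lag3, Tigit, Ctla4, Pdpn and Entpd1. For their mean, dilution as measured by the CD8 T cell identity genes is excluded as the whole cause. This does not hold for each member. On scaling to the identity genes Pdpn and Entpd1 had log2 changes of 0.92 and -0.50 and did not pass (limma, adjusted p = 0.0925 and 0.290). The mean level of the 7 differed by a further -1.45 ± 0.23 (SE) log2 units relative to the CD8 T cell identity genes (two-sided exact permutation p = 0.0159). Its size depends on the yardstick. The identity list changed by -0.55, but its members Cd3e and Cd8a by -1.20 and -1.15. Over the list alone, 7 of its 15 members were lower and 1 higher. For the other 17 receptors the difference relative to the identity genes was 0.40 ± 0.20 (p = 0.0952 by the same exact test) and decides nothing. Before this scaling, 11 of the 17 had log2 changes below 0 and 6 above it. For the whole list of 24 the value was -0.14 ± 0.20 (p = 0.476 by the same exact test). The list as a whole thus showed no detected fall beyond that of the identity genes. Its mean includes members that rose, among them Lair1 (log2 change 1.62) and 4632428N05Rik (0.73), which myeloid cells also make. Of the 24 members, 17 had log2 changes below 0 before this scaling and 7 above it. A mean over such a mix cannot show whether the receptors of T cells fell by dilution alone. The fall of the receptors did not rest on the library labelled WT replicate 2, since 7 members passed as lower without that library. Whether its label is wrong is not decided, as its Il27ra lay inside the IL27ra KO range. Its macrophage level of 2.79 lay outside the IL27ra KO range of 3.88 to 5.55. Its mean level of the 7 receptors that fell, a set with Cd244 in place of Pdpn, was 5.81. That lay outside the IL27ra KO range of 2.60 to 3.11. Neither value can settle the genotype, because both levels are outcomes of the comparison and the 7 receptors were picked for their fall. With the macrophage covariate the Lag3 difference went from -3.52 (SE 0.38) to -5.16 (SE 0.82) and its call ended because the SE widened, as that level runs with the genotype. A lower receptor level per cell and a smaller share of cells that carry the receptors may each underlie the fall, which bulk libraries do not separate and no test here addressed.

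Of the 51 interferon-stimulated genes, 12 were higher in the IL27ra KO libraries, and myeloid cells express many genes of this kind. Within the groups, the level of the 12 members that rose climbed with the macrophage level by 0.30 ± 0.13 (SE) log2 units per unit (exact permutation p = 0.0288), against a ratio of 0.49 between the rises of the 2 levels across the groups. The rise is therefore consistent with RNA of myeloid cells as a source. With the macrophage covariate the list stood at -0.12 relative to all genes, in a fit where that level runs with the genotype. An effect of the receptor on interferon responses in the T cells themselves stays open as untested.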
